A study of Homo sapiens with 6 samples.

How the data were processed

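The samples were 6 RNA preparations from HeyA8 cells, 3 untreated and 3 treated with MFH, grouped and numbered by their titles. Per the labels' protocols, biotin-labelled cRNA was made from total RNA by in vitro transcription, and per the submitters' processing notes the signals were exported with BeadStudio, whose version is not given in the sources used here. The deposited table holds a linear intensity per probe for each array, with no detection p and no control probes in the columns used here. A separate value table deposited by the authors holds log2 values of the same arrays. Its sorted columns differed by at most 0.001, as quantile normalization gives, each column had a median of 6.733, and its rank correlation with the linear intensities was 0.999999. The authors' steps between the tables are not stated, and the value table was used as an alternative only.

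Probes were named through the platform annotation, which dates from an older release. Symbols were updated by Entrez identifier with the RefSeq gene table of assembly GRCh38.p14 for 30074 probes. In all, 30113 probes carried 1 gene symbol, 8 several and 17110 none in the tables used here. Probes with several symbols or none stayed out of the gene test. No coordinates are given, since the build behind the array's design is not given in the sources used here.

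Linear intensities were corrected with normexp (offset 50) and quantile normalized between arrays in limma 3.58.1 under R 4.3.3, then taken to log2. An offset of this size pulls fold changes of dim probes towards 0. The design fixed before the data were examined called for negative controls or a detection p, and named this setting for a table with neither. Its filter needed a detection p, so a substitute was chosen after the file's columns were seen and before any result: background was estimated per array as the mode of the log2 signals, with the spread of the signals below the mode, and a probe was above background at a one-sided p of 0.05. Probes above background on at least 3 of the 6 arrays were kept, 21684 in all, of which 16213 had 1 symbol. The probe with the highest mean stood for a gene, which gave 11961 genes. Of 3350 genes with more than 1 kept probe, 4 had probes that passed in both directions.

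MFH was compared with untreated by lmFit and eBayes without covariates, with a two-sided test and Benjamini-Hochberg adjustment over the genes tested. Each SE of a log2 fold change is moderated: this fit draws a gene's variance towards a value shared by all genes. For genes whose arrays differ most, the SE is smaller than their own spread gives. A total of 29 gene lists were tested with camera (preset correlation 0.01), with camera with an estimated correlation, and with fry. Fry tests whether a list's genes move on balance one way. It passed 2 lists, heat shock (fry adjusted p = 4.35e-05) and chaperonin and prefoldin (fry adjusted p = 0.0118). The heat shock list was the only 1 of the 6 passing lists that also passed with an estimated correlation. Named genes were the 12 largest rises and the 12 largest falls among genes past the threshold with separated groups and no provisional symbol, up to 4 members per list with the largest changes among those past the threshold, and 14 genes fixed in advance whether or not they passed. Where there was no room for all list members, fewer were named. A lower bound of a fold was the mean of the bright group over the mean, per array, of the higher of the dim signal and the lowest signal above background.

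The procedure was tested on simulated arrays built from the real means and residual spreads, with 200 of 11961 genes changed above background, over 5 simulations. For this comparison, 31.9% of 67 genes changed 1.5-fold, 53.7% of 67 changed 2-fold and 88.8% of 66 changed 4-fold were recovered, with median estimated folds of 1.35, 1.59 and 2.90, so fold changes are understated. False calls made up 2.97% of calls. A list made only of raised genes passed camera at an unadjusted p under 0.05 in 5 of 5 simulations, and an unchanged list in 0. This shows that a list raised throughout is found, but 5 simulations are too few to give an error rate for lists. Noise was drawn separately for each probe, so genes of a simulated list did not vary together. In the data the estimated correlation was 0.483 for the mitotic list and 0.339 for the NF-kB list. The simulation therefore cannot check the tests of such lists. It also changed far fewer genes than the 2364 that passed in the data, so its share of false calls may not carry over. An earlier form of this simulation, which counted scale differences between arrays as noise and recovered fewer genes, was replaced by this one.

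Alternatives covered the background correction and its offset, the scaling, the authors' values, the filter, the probe rule, the variance model, array weights, a replicate block, a minimum fold of 1.5, and leaving out each array. Figures and checks used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No chip or scan date is in the columns used here, so no array batch could be tested.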

Results

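Gene expression was measured in HeyA8 cells, an established human ovarian cancer line, in 2 groups of 3 samples each. One group was untreated and the other had received magnetic fluid hyperthermia (MFH), in which a suspension of magnetic nanoparticles is heated by an alternating magnetic field. The question of the design was how expression in MFH-treated cells differs from that in untreated cells. The temperature, the duration, the particle dose and the time of harvest are not given in the sources used here, and particles without heating or heating without particles were not analysed here. Each of the 6 samples was hybridised to a 1-colour Illumina bead array with 47231 probes. Between 45.1% and 47.9% of probes lay above the estimated background of their array, and the background mode lay at intensities of 93.8 to 115. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.108. Nothing in the labels says that replicates came from separate cultures, so the spread between these samples may be technical. P-values of single genes measure that spread, moderated with the variances of all genes. Camera p-values with the preset correlation compare a list with the other genes at a fixed correlation, and are no measure of that spread.

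MFH-treated cells showed far higher levels of heat shock genes than untreated cells. HSPA6, a strictly stress-inducible member of the HSP70 chaperone family, rose by a log2 fold change of 5.81 ± 0.14 (moderated SE, n = 3 per group), which is 56.0-fold (limma adjusted p = 3.43e-13). Its normalised log2 level was 8.27 ± 0.12 (SD, n = 3) in untreated and 14.08 ± 0.34 (SD, n = 3) in MFH cells. A dimmer kept probe of HSPA6 rose by 5.04 ± 0.12 (SE), so the size of the rise depends on the probe. CRYAB, a small heat shock protein, rose by 4.54 ± 0.14 (SE), although it was above background on only 1 of the 3 untreated arrays. Its rise ranged from 3.87 to 6.73 over the alternative ways of processing. Smaller falls were found for 12 of 20 cytokine and NF-kB genes and 10 of 26 mitotic genes, and neither list passed with an estimated correlation (adjusted p = 0.623 and 0.807).

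Of 11961 genes tested, 936 were higher and 1428 lower in MFH cells at an adjusted p under 0.05 (limma, Benjamini-Hochberg), together 19.8% of genes tested. At least 2-fold changes were found for 105 genes that were higher and 35 that were lower, counts that depended on the processing: 72 and 18 in the authors' value table, 164 and 61 with offset 16, and 223 and 183 with the background mode subtracted. All 3 MFH arrays lay above all 3 untreated arrays for 1620 genes and below them for 2559, together 34.9% of genes, where chance alone gives 10%. The first principal component held 64.4% of the variance and separated the groups, and arrays of one group correlated at 0.991 to 0.996 against 0.978 to 0.984 across groups. The balance of directions depended on scaling: 39.6% of the genes past the threshold were higher after quantile normalization, against 62.4% (387 higher, 233 lower) with no normalization between arrays.

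**Figure D1:**
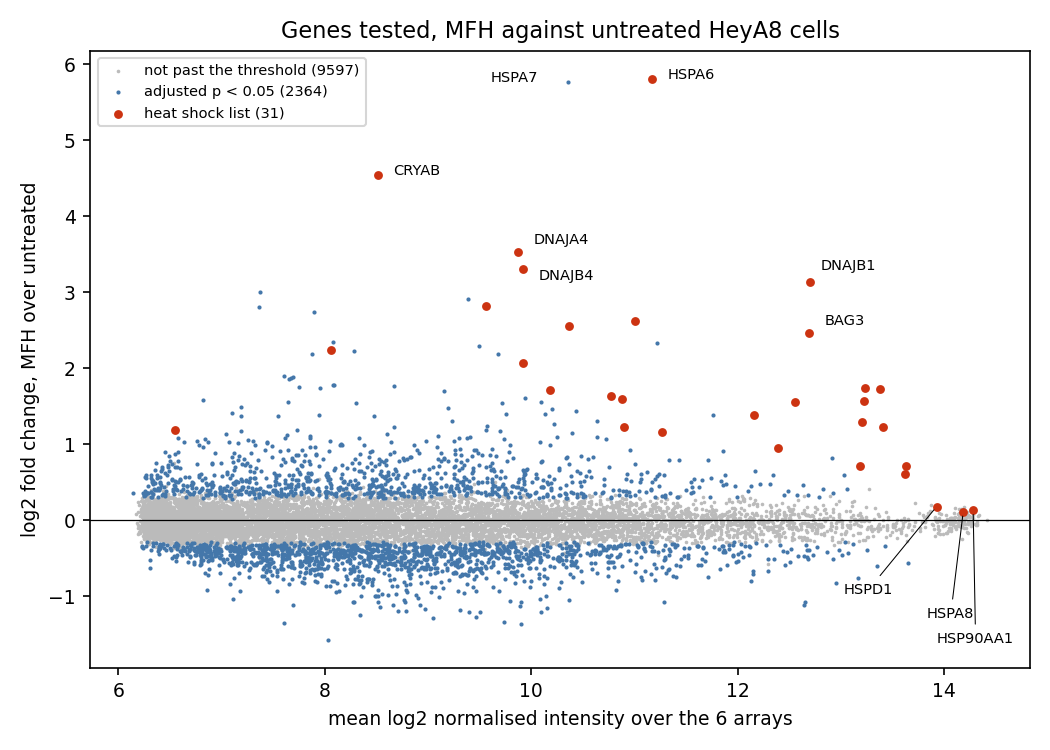
Log2 fold change (MFH over untreated) against mean log2 normalised intensity over the 6 arrays, with 1 point per gene, blue for the 2364 genes past the adjusted p threshold, grey for the other 9597 and red for the 31 genes of the heat shock list whether or not they passed. HSPA6 and HSPA7 stand highest at 5.81 and 5.77, and HSPA8, HSP90AA1 and HSPD1 lie near 0 at the bright end.

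The 12 largest rises among genes with separated groups included 7 members of the heat shock list. HSPA7, a near-identical relative of HSPA6 whose probe may not tell the pair apart, rose by 5.77. The co-chaperones DNAJA4, DNAJB4 and DNAJB1, which bring substrates to HSP70, rose by 3.53, 3.31 and 3.14. HSPA4L, an HSP110 family chaperone, rose by 2.82 and ZFAND2A, a zinc finger protein inducible by arsenite, by 2.63. The remaining 4 were PNLDC1, RPPH1, DHDH and RMRP. PNLDC1 and DHDH were not above background on any untreated array and were at least 5.92-fold and 5.50-fold higher in MFH cells, each measured against the lowest signal above background (adjusted p = 2.63e-07 and 2.95e-07). RPPH1, the RNA of RNase P, rose by 2.91 ± 0.24 (SE) and RMRP, the RNA of RNase MRP, by 2.75 ± 0.33 (SE), with RMRP above background on 2 of 3 untreated arrays. The SDs of RPPH1 and RMRP over the 3 MFH arrays were 0.75 and 1.04, a spread that the moderated SE understates. Over the alternatives RMRP ranged from 2.15 to 4.37, PNLDC1 from 2.38 to 4.63 and DHDH from 2.23 to 4.51.

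The heat shock list, written before the data were examined like the other lists and the rule for naming genes, held 31 tested genes, of which 28 were higher and 0 lower. The count was also 28 when adjusted over the list alone. The median log2 fold change was 1.59 (camera adjusted p = 1.22e-50, and adjusted p = 0.0237 with an estimated correlation), and for all 28 genes every MFH array lay above every untreated array. BAG3, an HSP70 co-chaperone, rose by 2.47 ± 0.10 (SE), HSPH1 by 1.72 ± 0.12 and HSPB1 by 1.22 ± 0.10. HSPA1B and HSPA1A, near-identical genes whose probes may share signal, rose by 1.74 and 1.58. The MFH means of HSPA6, DNAJB1, BAG3, HSPA1A, HSPA1B, HSPH1 and HSPB1, 13.92 to 14.27, lay near that of the brightest probe of HSPD1 (14.02), a gene whose dimmer probes rose more than this probe did, so the sizes of these 7 rises are less certain than their SE states. The 3 genes that did not pass were HSPA8 (0.11, adjusted p = 0.529), HSP90AA1 (0.13, adjusted p = 0.418) and HSPD1 (0.18). For HSPD1, the mitochondrial chaperonin, 2 dimmer probes not standing for the gene rose by 1.41 and 1.73, so the value of its brightest probe does not represent all its probes.

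**Figure D2:**
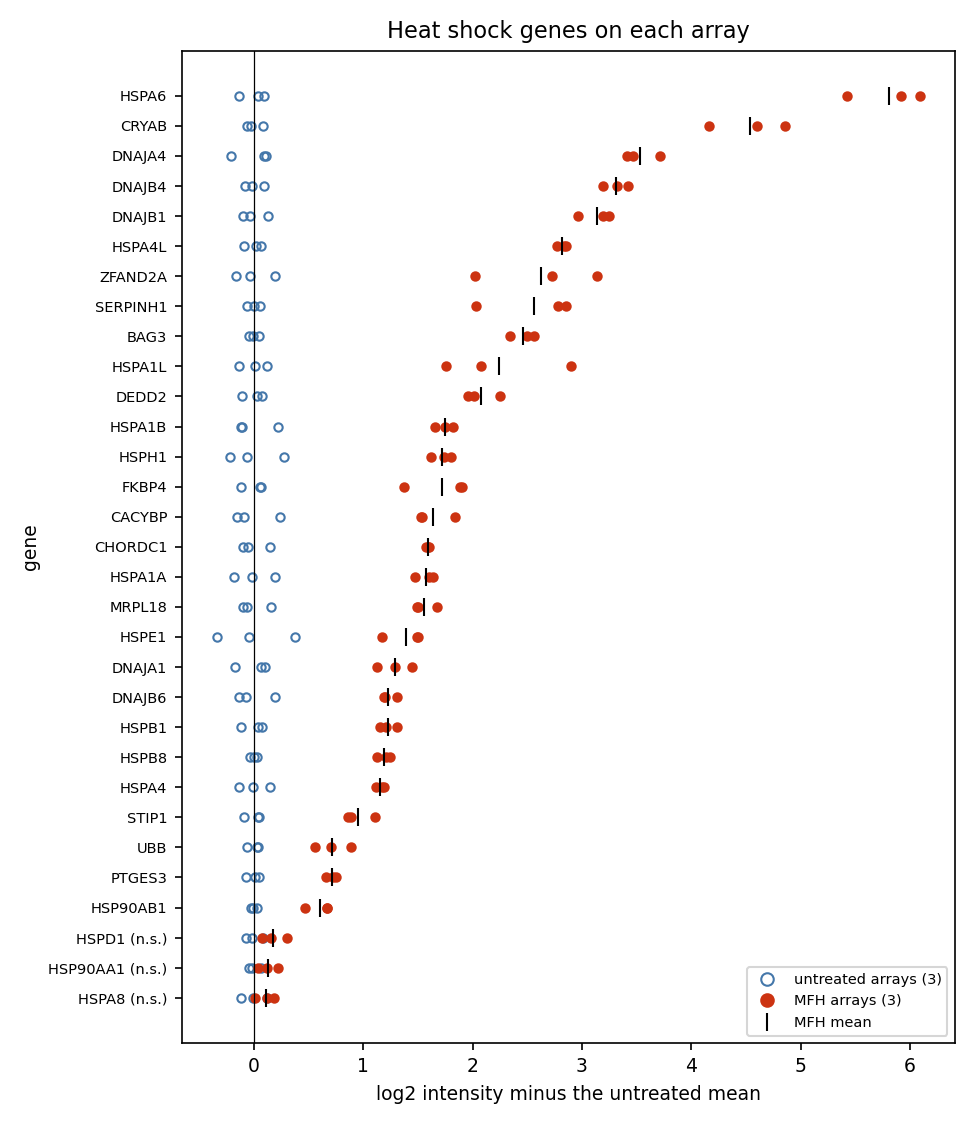
Log2 intensity of each heat shock gene on each array minus the gene's untreated mean, with open blue circles for the 3 untreated arrays, red circles for the 3 MFH arrays and a black bar for the MFH mean. For 28 genes the MFH arrays lie above the untreated arrays, while the 3 genes marked n.s. overlap.

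Other protein-folding genes rose in smaller numbers. Of 14 subunits of the cytosolic chaperonin and of prefoldin, which fold newly made proteins, 5 were higher and 0 lower, and 6 were higher when adjusted over the list alone (camera adjusted p = 4.38e-04; adjusted p = 0.417 with an estimated correlation). The list passed fry (adjusted p = 0.0118), though not camera with an estimated correlation. CCT5 rose by 0.99 ± 0.12 (SE), CCT6A by 0.91 ± 0.10 and TCP1 by 0.82 ± 0.10, or 1.53 for TCP1 with the mean of its probes. Among 19 genes of endoplasmic reticulum folding, 3 were higher and 0 lower and the list did not pass (adjusted p = 0.557). HSPA5, the main HSP70 of that compartment, rose by 1.38 ± 0.13 (SE) and XBP1, a transcription factor of the unfolded protein response, by 0.51 ± 0.10. Of 32 proteasome subunits, 3 were higher and 1 lower (adjusted p = 0.604).

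Among 28 genes of the integrated stress response, most of them targets of the transcription factor ATF4, 8 were higher and 1 lower (11 and 2 when adjusted over the list alone). The list passed camera with the preset correlation (adjusted p = 3.81e-03) but not with an estimated correlation (adjusted p = 0.807). STC2, a secreted glycoprotein, rose by 0.96 ± 0.13 (SE), and SLC3A2, the heavy chain of amino acid transporters, by 0.55 ± 0.12. ATF3 had a log2 fold change of 0.33 (adjusted p = 0.290). DDIT3 had 0.38 (adjusted p = 0.0794), with adjusted p in a range of 0.0196 to 0.296 over the alternatives. It passed without MFH replicate 1 (0.52, adjusted p = 0.0196), with array weights (0.41, adjusted p = 0.0330) and with the replicate number as a block (0.38, adjusted p = 0.0426). Of 6 metallothionein-list genes, which bind or export zinc, 4 were higher and 0 lower, also when adjusted over the list alone (camera adjusted p = 0.0206; adjusted p = 0.544 with an estimated correlation). That call was lost without untreated replicate 2 (adjusted p = 0.0736, in a range of 0.0105 to 0.0736 over alternatives with the preset correlation), and each of the 4 genes lost its own call without at least 1 of the arrays. Of 21 p53 targets, 5 were higher and 0 lower (5 and 1 when adjusted over the list alone), and the list did not pass (adjusted p = 0.0784), though it did without untreated replicate 1 (adjusted p = 0.0487), without MFH replicate 1 (adjusted p = 0.0165), under 75th percentile scaling (0.0473) and with no filter (0.0411), in a range of 0.0165 to 0.279 with the preset correlation. MDM2, the ubiquitin ligase that restrains p53, rose by 0.97 ± 0.11 (SE) and GADD45A by 0.61 ± 0.11.

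Of 20 genes of NF-kB signalling and cytokines, 12 were lower and 0 higher, also when adjusted over the list alone, with a median log2 fold change of -0.47 (camera adjusted p = 3.40e-06; adjusted p = 0.623 with an estimated correlation). The chemokine CXCL2 fell by 1.36 ± 0.19 (SE), NFKB2, an NF-kB subunit, by 1.01 ± 0.10 and IL1B by 0.83 ± 0.17, though IL1B lost its call with an intensity trend and robust variance (adjusted p = 0.0627, in a range of 4.75e-04 to 0.0784). CXCL8 fell by 0.76 ± 0.19 (SE), a call lost without untreated replicate 2 (adjusted p = 0.0645, in a range of 9.30e-04 to 0.165 over the alternatives). MFH replicate 1 was the lowest array for CXCL2, IL1B and CXCL8, and without it CXCL8 had -0.50 (adjusted p = 0.0354) and the list median was -0.39 (camera adjusted p = 5.19e-05, in a range of 2.00e-08 to 1.04e-04 with the preset correlation). The MFH arrays also stood apart from each other on the second principal component, at 12.6, -0.86 and -13.6. Of 26 mitotic genes, 10 were lower and 0 higher, also when adjusted over the list alone, with a median of -0.22 (camera adjusted p = 1.87e-04; adjusted p = 0.807 with an estimated correlation). CENPA, the centromeric histone, fell by 0.95 ± 0.11 (SE), and the mitotic kinases AURKB and AURKA fell by 0.75 ± 0.12 and 0.62 ± 0.12, with the call of AURKA lost without normalization between arrays (adjusted p = 0.110, in a range of 4.24e-04 to 0.110).

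The 12 largest falls were smaller than the largest rises. SCARNA9, a small Cajal body RNA, fell by 1.57 ± 0.19 (SE), the Polycomb protein gene CBX2 by 1.36 ± 0.11, the collagen gene COL6A1 by 1.34 ± 0.15, NACC2 by 1.29 ± 0.10 and the kinase gene PRKCD by 1.27 ± 0.11. Over the alternatives SCARNA9 ranged from -2.21 to -1.30 and CBX2 from -2.19 to -1.12. RAB40C, WNT5B, LRP8, KLF13 and CCNF fell by 1.25, 1.21, 1.21, 1.20 and 1.19. CSF3, a haematopoietic growth factor, fell by 1.20 ± 0.30 (SE, adjusted p = 9.84e-03), and its call was lost with an intensity trend and robust variance (adjusted p = 0.220, in a range of 3.30e-05 to 0.220). Its SD over the MFH arrays was 0.92, a spread that the moderated SE understates. Without MFH replicate 1, its lowest array, CSF3 had -0.70 (adjusted p = 0.0148).

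**Figure D3:**
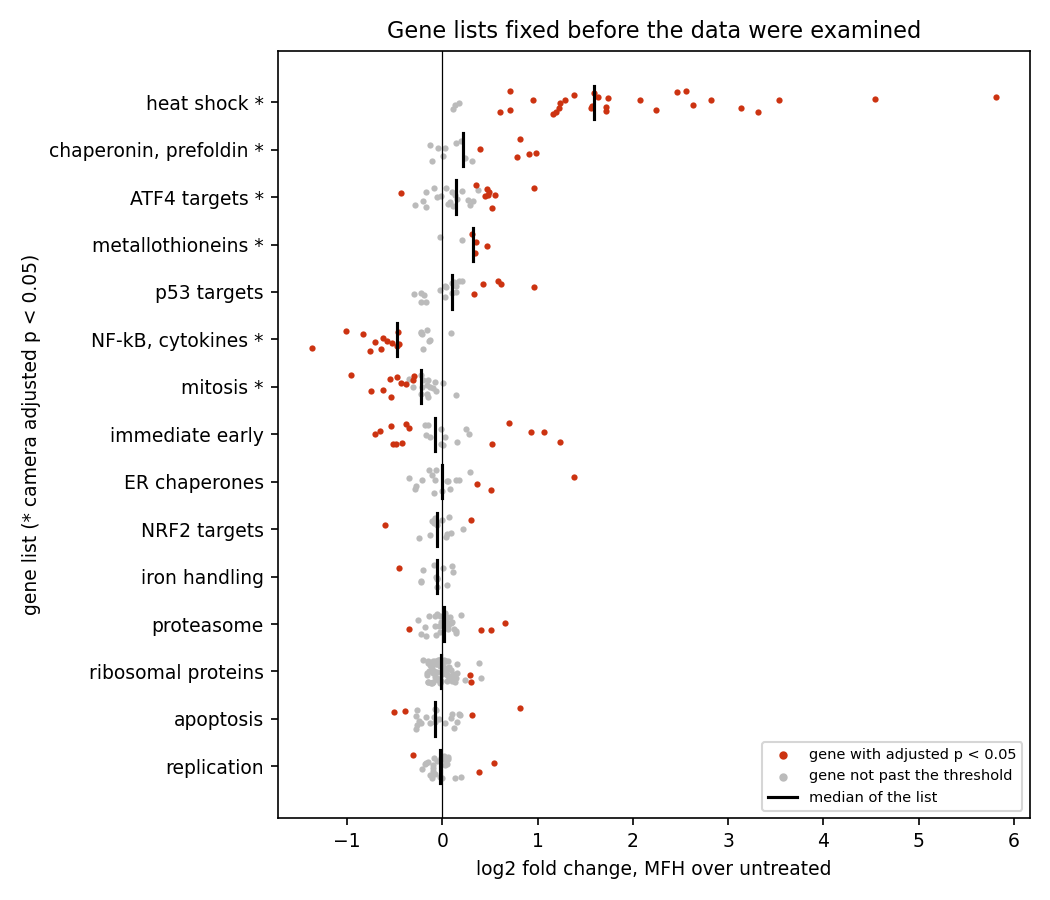
Log2 fold change (MFH over untreated) of each tested member of 15 of the 29 gene lists, red for genes past the adjusted p threshold and grey for the others, with a black bar at each list's median and a star at the 6 lists that passed camera with the preset correlation. The heat shock median lies at 1.59, and the sign of the ribosomal protein median turns from -0.01 to 0.07 under 75th percentile scaling.

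The other lists did not pass camera. Immediate early genes moved both ways, with 5 higher and 8 lower of 24 (adjusted p = 0.878). The transcription factor gene KLF4 rose by 1.24 ± 0.15 (SE) and IER5, a regulator of heat shock factor 1, by 1.07 ± 0.13, while JUNB fell by 0.71 ± 0.16, a call lost with the background mode subtracted (adjusted p = 0.0944, in a range of 2.74e-05 to 0.0944). Matrix and epithelial-mesenchymal genes also split, with 3 higher and 4 lower of 19 (adjusted p = 0.706). THBS1, a matrix glycoprotein, rose by 1.73 ± 0.12 (SE) and ITGA5, the fibronectin receptor subunit, fell by 1.03 ± 0.10. Hypoxia and glycolysis genes had 4 higher and 2 lower of 20 (adjusted p = 0.668), with P4HA2 up by 0.70 ± 0.11 (SE). Apoptosis regulators had 2 higher and 2 lower of 24 (adjusted p = 0.878), with PMAIP1, a BH3-only protein, up by 0.81 ± 0.11 (SE). Autophagy and lysosome genes had 3 higher and 1 lower of 20 (adjusted p = 0.626).

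Genes of the oxidative stress and iron lists seldom passed the threshold. Of 16 NRF2 targets 1 was higher and 1 lower (adjusted p = 0.911), and of 13 iron-handling genes 0 were higher and 1 lower (adjusted p = 0.706). NQO1, a quinone reductase, fell by 0.60 ± 0.10 (SE), a call lost without normalization between arrays (adjusted p = 0.139, in a range of 6.19e-05 to 0.139). HMOX1, the inducible haem oxygenase, had a log2 fold change of 0.05 ± 0.21 (SE, adjusted p = 0.915), and 0.41 without untreated replicate 3 (adjusted p = 0.0416, in a range of 0.0416 to 0.973). TFRC, the transferrin receptor, had -0.20 ± 0.11 (SE, adjusted p = 0.267). FTH1 was not analysed here.

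Replication genes had 2 higher and 1 lower of 27 (adjusted p = 0.911), histones 1 and 4 of 42 (adjusted p = 0.557), and DNA repair genes 0 and 3 of 19 (adjusted p = 0.485). Splicing and stress granule genes had 0 higher and 3 lower of 19 (adjusted p = 0.557), sterol synthesis genes 0 and 2 of 14 (adjusted p = 0.911), and interferon-stimulated genes 0 and 2 of 19 (adjusted p = 0.878). Ribosomal protein genes had 2 higher and 0 lower of 72 (adjusted p = 0.762, and 0.0170 under 75th percentile scaling), and respiratory chain genes 1 and 2 of 73 (adjusted p = 0.974). Among markers of other cell types, leukocyte genes had 1 higher and 0 lower of 7, fibroblast genes 2 and 1 of 4 (adjusted p = 0.557 for both), and endothelial and red cell genes 0 and 0 of 4 (adjusted p = 0.878). Epithelial markers had 0 higher and 2 lower of 9 (adjusted p = 0.911), with the ovarian lineage factor PAX8 at -0.64 ± 0.10 (SE), a call lost without normalization between arrays (adjusted p = 0.0718, in a range of 4.84e-05 to 0.0718). Reference genes had 1 higher and 0 lower of 13 (adjusted p = 0.773). Adjusted over the list alone, counts grew for immediate early genes (6 higher and 8 lower), sterol synthesis genes (0 and 4), epithelial markers (1 and 2) and p53 targets, and stayed or shrank for the rest of the lists that did not pass. Median, mean and test differed in sign for 9 of these 23 lists.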

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

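The test of unnamed probes was chosen after the data were seen. Probes without a gene name in the tables used here lay outside the gene comparison and still carried signal that differed between the groups. Of 5471 such probes above background, 257 were higher and 179 lower in MFH cells (limma, Benjamini-Hochberg over all kept probes), of which 44 and 3 changed at least 2-fold. The largest rises were those of probes ILMN_2252160 (3.21 ± 0.10 SE) and ILMN_1757278 (2.53 ± 0.20 SE), and the largest falls those of ILMN_2364022 (-1.16 ± 0.11 SE) and ILMN_1764571 (-1.10 ± 0.11 SE). Their genes were not identified here.

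Other splits of the 6 arrays into 3 and 3 were planned before the data were examined. The real split gave 2364 genes past the threshold and 140 at least 2-fold changed, and the highest other split gave 0 of each. For gene lists the real split passed 6 and the other splits 2 to 5. Each other split mixed arrays of both groups. The treatment difference thus stayed partly in its contrast and otherwise widened its residual spread. Counts from these splits, the 0 genes included, are therefore no measure of counts without treatment. In each of the 3 counts, 1 of the 10 splits, the real one, reached the real value, and 10 splits are too few for a share under 0.05.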

How the results depend on the processing

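The offset of 16, the subtraction of the background mode and the test of every probe were chosen after seeing the data. Normexp with offset 50, planned as an alternative, is the setting used, and a chip block was not run for want of barcodes. No named gene or list past a threshold reversed. Without normalization between arrays 387 genes were higher and 233 lower. The authors' value table gave 18 genes at least 2-fold lower. With offset 16, 164 genes were at least 2-fold higher and 61 lower. With the background mode subtracted 588 were higher and 923 lower, and 223 and 183 at least 2-fold so. Every probe on its own gave 186 at least 2-fold higher. With an estimated correlation 1 list passed. The cause was not tested, except that a smaller offset shrinks dim probes less and that testing probes counts more features. Leaving out 1 array gave 651 to 850 genes higher, 1010 to 1293 lower, 88 to 116 and 30 to 48 at least 2-fold higher and lower, 5 to 7 lists and a heat shock median of 1.55 to 1.67. The replicate number as a block gave 2218 genes past the threshold, 2160 of them shared with the fit without it. Deviations of same-numbered arrays correlated at 0.0075, 0.0451 and -0.0666, and those of other-numbered arrays across groups at -0.122 to 0.098. No effect shared by equal numbers was seen, but these values cannot show whether such arrays shared a culture or a day. DDIT3 passed under the block (adjusted p = 0.0426, in a range of 0.0196 to 0.296). Of 111 named genes past the threshold 55 kept their call in every alternative run, as did 23 of the 24 largest rises and falls, CSF3 being the exception, although RMRP and CRYAB were tested in 17 and PNLDC1 and DHDH in 14 of the 18, having failed the filter in the others; 48 lost it without normalization between arrays. Low signal over background limits dim genes.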

Other observations

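The tests of small RNAs and of neighbouring genes, and the tests of gene families, were chosen after results were seen, except the first test of 1 array below. Whether probe signals of small structured non-coding RNAs follow the amounts of these RNAs was not tested. Their signals moved in MFH cells in ways the lists did not cover. Of 174 tested (by RefSeq class, assembly GRCh38.p14, which leaves out SCARNA9), 36 were higher and 7 lower. The class also holds RNA18SN5 (-0.08) and RNA28SN5 (0.15), the 18S and 28S ribosomal RNAs, which are not small and were not called. They stayed in the counts and medians of small RNAs below, among the RNAs set against those of polymerase III. Besides RPPH1 and RMRP, named here after their values were seen, RNA5S9 (5S ribosomal RNA) rose 5.02-fold, and on the log2 scale RNU6ATAC (a minor spliceosome RNA) rose by 1.86 ± 0.29 (SE) and VTRNA1-2 (a vault RNA) by 1.18 ± 0.18.

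These 5 are transcripts of RNA polymerase III, and a higher level of that class is a hypothesis. Without these 5, 10 polymerase III RNAs had a median log2 fold change of 0.30 against 0.08 for 159 other small RNAs (two-sided permutation p = 0.0229 across genes, which are not independent), a form chosen after all members' values and 2 earlier forms were seen, with all 15 (p = 3.00e-05) and with VTRNA1-2 kept (p = 0.00151). A shift of the whole class above 0.5 from RNA quality or labelling is argued against by its median of 0.10 and 7 falls. That bound was set after results were seen. The class still leaned upward, with 36 of 174 higher and 7 lower, against 936 and 1428 of 11961 genes tested. A smaller or partial effect of RNA quality or labelling therefore stays open. The test fixed beforehand favoured MFH replicate 1, the array highest in these RNAs, as the cause. Without that array 17 of the 36, fewer than 50%, kept a log2 fold change of 0.5, but only 24 of them reached 0.5 with all arrays. A refit of all genes without it was chosen after that result. It found 28 of 169 small RNAs higher and 3 lower (16.6% higher, against 6.04% of other genes, exact p = 1.56e-06). The exact test takes the RNAs as independent, which they are not. The refit argues against MFH replicate 1 as the whole cause, but a contribution from that array stays open. Means of the 36, picked because they rose, were 8.78, 8.48 and 8.29 on MFH replicates 1 to 3. They were 7.64 to 7.82 on the untreated arrays.

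HSPA8, HSP90AA1 and HSPD1 did not pass although 28 other heat shock genes did, and signal near the top of the scale is a candidate explanation. It was tested on other kept probes of each gene that were at least 1 log2 unit dimmer. For HSPD1, 2 of 2 dimmer probes rose (1.41 and 1.73), as a signal near the top of the scale would give. For HSP90AA1, 0 of 1 such probes rose (-0.24), which argues against this explanation by the bound set beforehand. Its other kept probe, nearly as bright (14.05 in untreated cells), had -0.07. Dimmer probes can miss a change, however, as those of CACYBP did (0.13 and 0.19 on the log2 scale, where the gene rose 3.11-fold). For HSPA8 there was no such probe (0 of 0), so the explanation stays open. Its other kept probe, nearly as bright (13.995 in untreated cells), had 0.13 and was not called. Whether the rises of called heat shock genes as bright in MFH cells, HSPA6 among them, are compressed in the same way was not tested. Dimmer probes of such genes went both ways: 1.48 against 0.72 for the brighter probe of UBB, but 5.04 against 5.81 for HSPA6. In untreated cells the dimmer HSPA6 probe lay at 6.88, a dim level where the offset pulls fold changes towards 0. Its smaller rise therefore does not argue against compression at the top of the scale. No biological explanation was tested.

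Genes beside induced heat shock genes were examined because PNLDC1 lies next to MRPL18, a heat shock list member (RefSeq, GRCh38.p14). Within 10 kb of 24 heat shock genes raised at least 2-fold lay 21 other tested genes, of which 3 were higher (PNLDC1, TCP1 and SNORA20, all beside MRPL18; one-sided permutation p = 0.0909) and 2 lower (ITFG2 and POU2F2). Without PNLDC1, which prompted the test, 2 of 20 were higher (10%, against 7.60% of other genes; one-sided permutation p = 0.231). Transcription that continues past induced genes may contribute, but the test misses the threshold and its rises come from 1 locus, so it stays open. The positions used held no strand, so the test cannot tell a gene downstream of an induced gene from one upstream. TCP1 also belongs to the chaperonin list, of which 5 of 14 genes were higher. The bound against it was first a p of 0.05 or more and was changed, after 0.0909 was seen, to a share at or below that of other genes, since a missed threshold does not show that shares are equal. Whether probes share sequence was not tested.

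In 8 Fisher's exact tests of 4 gene families outside the heat shock and endoplasmic reticulum lists, none passed after Benjamini-Hochberg adjustment. Solute carriers came closest, with 36 of 209 lower (17.2%, against 11.8% of other genes; exact p = 0.0232, adjusted p = 0.185), and 4 of 28 other J-domain genes were higher (exact p = 0.274, adjusted p = 0.438).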
